A study of Mus musculus with 8 samples.

How the data were processed

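The libraries came from tissue labelled whole brain of 3-month-old male mice, 4 labelled wild type (WT) and 4 labelled Nsun5 knockout (KO), each numbered 1 to 4 within its group. The extraction notes describe nuclease digestion of the lysate, isolation of ribosome-bound fragments, removal of ribosomal RNA, gel purification and PCR-enriched libraries. The submitters' notes name TopHat2 and the mouse genome build mm10 without a version or a role, and the counting program, the annotation release and any filter are not stated in them.

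The deposited gene table holds raw counts for 54532 Ensembl genes of all classes in 8 footprint libraries and in 8 mRNA libraries with matching names. Its values are whole numbers with a different total in each library, so no normalization had been applied. The deposited gene length in that table is in bases and was used by the authors for the 2 normalized tables. These 2 tables hold RPKM made by the authors, 1 for footprints and 1 for mRNA. Dividing counts by length and RPKM gave 1 library size per column, and that size equalled the DESeq2 size factor times the geometric mean total, computed within each kind of library. The footprint libraries held 0.586 to 3.49 M gene-assigned counts (M, mega), 0.233 to 1.47 M of them on protein-coding genes, and the mRNA libraries 15.6 to 17.8 M. The footprint size used for RPKM differed from the library total by a factor of 0.687 to 1.54.

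Counts of each kind were fitted with edgeR 4.0.16 in R 4.3.3, with TMM library sizes and the quasi-likelihood test, KO against WT, with positive log2 fold changes meaning a higher level in KO. Footprint genes were kept by filterByExpr with its default minimum count of 10. mRNA genes were kept at a mean RPKM of at least 1, and the translational efficiency test took genes with a mean RPKM of at least 1 in both kinds of library. The change in translational efficiency was the interaction of genotype and library kind in 1 edgeR model of all libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. For mRNA and translational efficiency, limma 3.58.1 on log2 RPKM with a pseudocount of 0.1 had been chosen first. The finding that the table holds counts of both kinds led to edgeR for these comparisons before any test was run, and the limma fits were kept as alternatives.

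For 30 lists of brain cell types, regions and pathways with 598 entries, camera with a preset correlation of 0.01 compared each list's genes with all other genes tested, for lists with at least 3 measured members. The lists, the tests, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named Nsun5, up to 10 genes per direction among those past the threshold or, where fewer than 5 passed, the 5 with the lowest unadjusted p per direction as not passing, and up to 4 members of each list described. Predicted genes were counted but not named. Per-gene levels are CPM of the TMM library size, and a list's level in a library is the mean log2 CPM of its genes with a prior count of 2. Shares, totals and list levels were compared by exact two-sided permutation over all 70 splits of 4 against 4, for which the smallest possible p is 0.0286.

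The alternatives were DESeq2 1.42.0, 2 other library scalings, other filters and pseudocounts, limma on RPKM, quantile normalization, a replicate block, limma-voom, camera with an estimated correlation, fry, and leaving out each library in turn. The labels do not say that a replicate number pairs a WT with a KO library, so the model was not blocked. Across genes, the deviations of same-number WT and KO libraries from their group means correlated at −0.343 to −0.010 in footprints and at −0.343 to 0.123 in mRNA. These values showed no sign of pairing but cannot exclude it. Footprint and mRNA libraries of 1 number correlated at −0.154 to 0.226, and 6 of 8 footprint libraries were closest to the mRNA library of their own number. A replicate block and a fit of the log2 ratio per number were among the alternatives. Tested on simulated data of the same depth and spread, edgeR recovered 4% of 1.5-fold changes in footprints, 57% in mRNA and 15% in translational efficiency. At 3-fold it recovered 70%, 92% and 76%. False calls were 7.5%, 6.88% and 9.90% of the calls. A simulated shift of −0.40 in the myelin list came back as −0.38, with 1 other list called. The simulated genes were drawn independently, while the estimated correlation within the myelin list was 0.50 in mRNA. The simulation therefore does not show how often lists are called falsely in these data. Read lengths, positions within transcripts and reading frame were not analysed here, so a footprint count is a read count of the footprint library.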

Results

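Ribosome profiling, which sequences the RNA fragments that ribosomes shield from nuclease, was done on tissue labelled whole brain from 3-month-old male mice labelled wild type (WT) or knockout (KO) for Nsun5, an enzyme that methylates a cytosine in ribosomal RNA. The question is how loss of this enzyme acts on transcript levels and translation in the brain, with myelin and sleep as the traits the series names. There were 4 WT and 4 KO footprint libraries, and each had an mRNA library of the same name. The labels do not tie a library to an animal. The protocol names 5 mice per genotype, so the p-values measure the spread between these libraries.

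Footprint libraries of the KO group were shallower. WT libraries 1 to 4 held 1201263, 2835358, 3493841 and 2926597 counts assigned to genes, and KO libraries 1 to 4 held 1236851, 1296876, 586392 and 1230192. The means were 2.61 ± 0.986 M counts (M, mega) in WT and 1.09 ± 0.335 M in KO (SD, n = 4 each, exact permutation p = 0.114). Protein-coding genes took 48.2% ± 13.8 of the footprint counts in WT and 42.9% ± 15.5 in KO. MicroRNAs, which are not translated, took 41.1% ± 14.6 in WT and 47.5% ± 15.9 in KO (SD, n = 4). Mir128-1, a neuronal microRNA, held 15.4% and Rny1, a small cytoplasmic RNA, 7.10% of all footprint counts. The mRNA libraries held 15642086 to 17829523 counts, of which 97.7% were on protein-coding genes in both groups. The median standard error of a gene's log2 fold change was 0.29 for footprints, 0.11 for mRNA and 0.30 for translational efficiency.

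**Figure D1:**
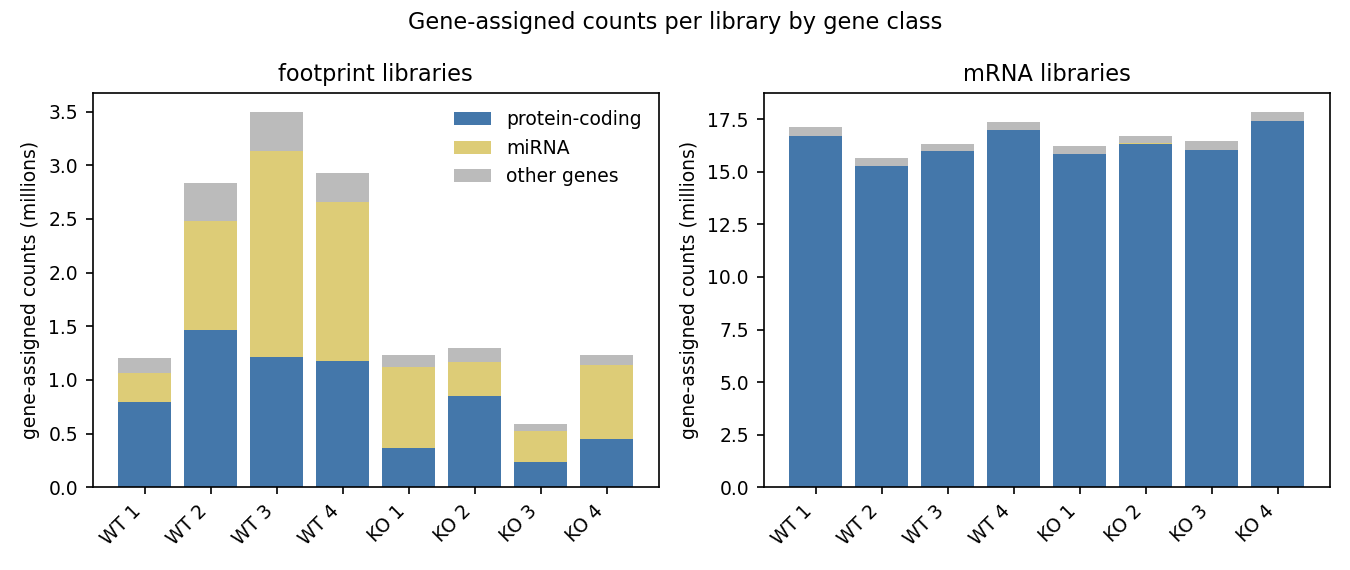
Gene-assigned counts (M, y axis) of each library (x axis), stacked by gene class, for footprint libraries on the left and mRNA libraries on the right. Footprint totals range from 0.586 to 3.49 M with a large microRNA part, and mRNA totals from 15.6 to 17.8 M.

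Nsun5 mRNA did not separate the groups. Nsun5 (ENSMUSG00000000916, mm10 chromosome 5, 135369953 to 135376805) had 91, 82, 103 and 109 mRNA counts in WT libraries 1 to 4 and 102, 124, 83 and 110 in KO libraries 1 to 4. The mRNA log2 fold change was 0.12 ± 0.15 (SE, n = 4 each, edgeR adjusted p = 0.820), with a 95% interval from −0.17 to 0.41. Footprints on Nsun5 were too few to compare, with 2, 11, 0 and 6 counts in WT and 3, 0, 1 and 2 in KO (log2 fold change −0.22 ± 0.92, edgeR adjusted p = 0.991). Gene counts would not show a small deletion or a point change, so the directions given here are between libraries as labelled.

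Footprints on the mitochondrial genome's transcripts, which encode respiratory chain subunits, were higher in the KO libraries. All 9 measured genes had a positive change, with a median log2 fold change of 0.71, and mt-Nd2 had 460 ± 83.8 CPM in WT and 1097 ± 606 in KO (SD, n = 4). Footprints on myelin and mature oligodendrocyte transcripts were lower (17 of 22 genes, median −0.22), and so were those on axon node and neurofilament transcripts (14 of 15 genes, median −0.21). These 3 lists, 1 higher and 2 lower, were the ones that passed camera among the 25 tested on footprints, and 0 passed by camera with an estimated correlation (lowest adjusted p = 0.634) or by fry (0.297). No single gene passed edgeR among 8476, with 468 at an unadjusted p under 0.05 where 424 are expected by chance if the model holds. Splits of 4 against 4 with as many WT as KO libraries on each side gave 210 to 515. DESeq2 called 4 genes, all higher (Snord90, Cinp, Mir3099 and Mrpl20), and limma on RPKM called 5 others, all lower (the microRNAs Mir7049, Mir6907, Mir6915 and Mir5128 and a predicted gene). With protein-coding genes only, edgeR called Yipf1 (adjusted p = 0.00184), mt-Nd2 (0.0303) and Cinp (0.0363), all higher.

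In the mitochondrially encoded list, 0 of 9 genes passed over all genes and 6 passed when adjusted over the list alone. mt-Nd2 had a log2 fold change of 1.25 ± 0.33 (SE, n = 4 each, edgeR adjusted p = 0.863), mt-Nd5 of 1.18 ± 0.35, mt-Nd4 of 0.94 ± 0.31 and mt-Nd6 of 0.82 ± 0.25. The list's adjusted p was 5.75e-07 by camera and 0.634 with an estimated correlation, and without KO library 3 the median was 0.37, with mt-Nd2 at 0.83, mt-Nd5 at 0.73 and mt-Nd4 at 0.57. The list's footprint level per library was 8.01 ± 0.27 log2 CPM in WT and 8.71 ± 0.74 in KO (exact permutation p = 0.114, n = 4), and KO library 2 lay within the WT range. In the myelin list, Mal, a myelin membrane protein, had 102 ± 25.1 CPM in WT and 67.4 ± 5.77 in KO, and Mbp, a main protein of compact myelin, 225 ± 23.6 and 175 ± 16.2 (SD, n = 4). 0 of its 22 genes passed, over all genes or adjusted over the list alone. In the axon list, Nefh, the heavy neurofilament chain, had a log2 fold change of −0.47 ± 0.20. 0 of its 15 genes passed, over all genes or adjusted over the list alone. Both lists had adjusted p = 0.00972 by camera and adjusted p = 0.634 with an estimated correlation. The myelin call ended without WT library 4 (adjusted p = 0.0702), KO library 1 (0.119), KO library 2 (0.0566) or KO library 3 (0.0701), and the axon call without WT library 3 (0.0628), WT library 4 (0.0702), KO library 3 (0.0798) or KO library 4 (0.0562).

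The genes with the lowest footprint p did not pass edgeR and are given as values. Mrpl20, a protein of the mitochondrial ribosome (ENSMUSG00000029066, chromosome 4, 155802878 to 155809975), had 19.8 ± 3.54 CPM in WT and 42.2 ± 3.98 in KO (SD, n = 4), a log2 fold change of 1.08 ± 0.21 (SE, edgeR adjusted p = 0.638). Yipf1, a Golgi membrane protein (ENSMUSG00000057375, chromosome 4, 107314363 to 107359823), had 268 ± 141 and 1180 ± 692 footprint CPM against 29.8 ± 2.15 and 29.1 ± 0.973 mRNA CPM, with a footprint log2 fold change of 2.14 ± 0.44. Cinp (1.27 ± 0.26), the small nucleolar RNA Snord90 (2.17 ± 0.45) and the microRNA Mir3099 (1.56 ± 0.35) were the others on the higher side. On the lower side stood Ndufb11, a subunit of respiratory complex I (−0.78 ± 0.18), Satb1, a chromatin organizer (−0.89 ± 0.23), Nrn1, which promotes neurite growth (−0.80 ± 0.21), Tmem63a, a mechanosensitive channel of oligodendrocytes (−1.08 ± 0.29), and Rmnd5b (−0.74 ± 0.20). All 5 had edgeR adjusted p = 0.863.

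**Figure D2:**
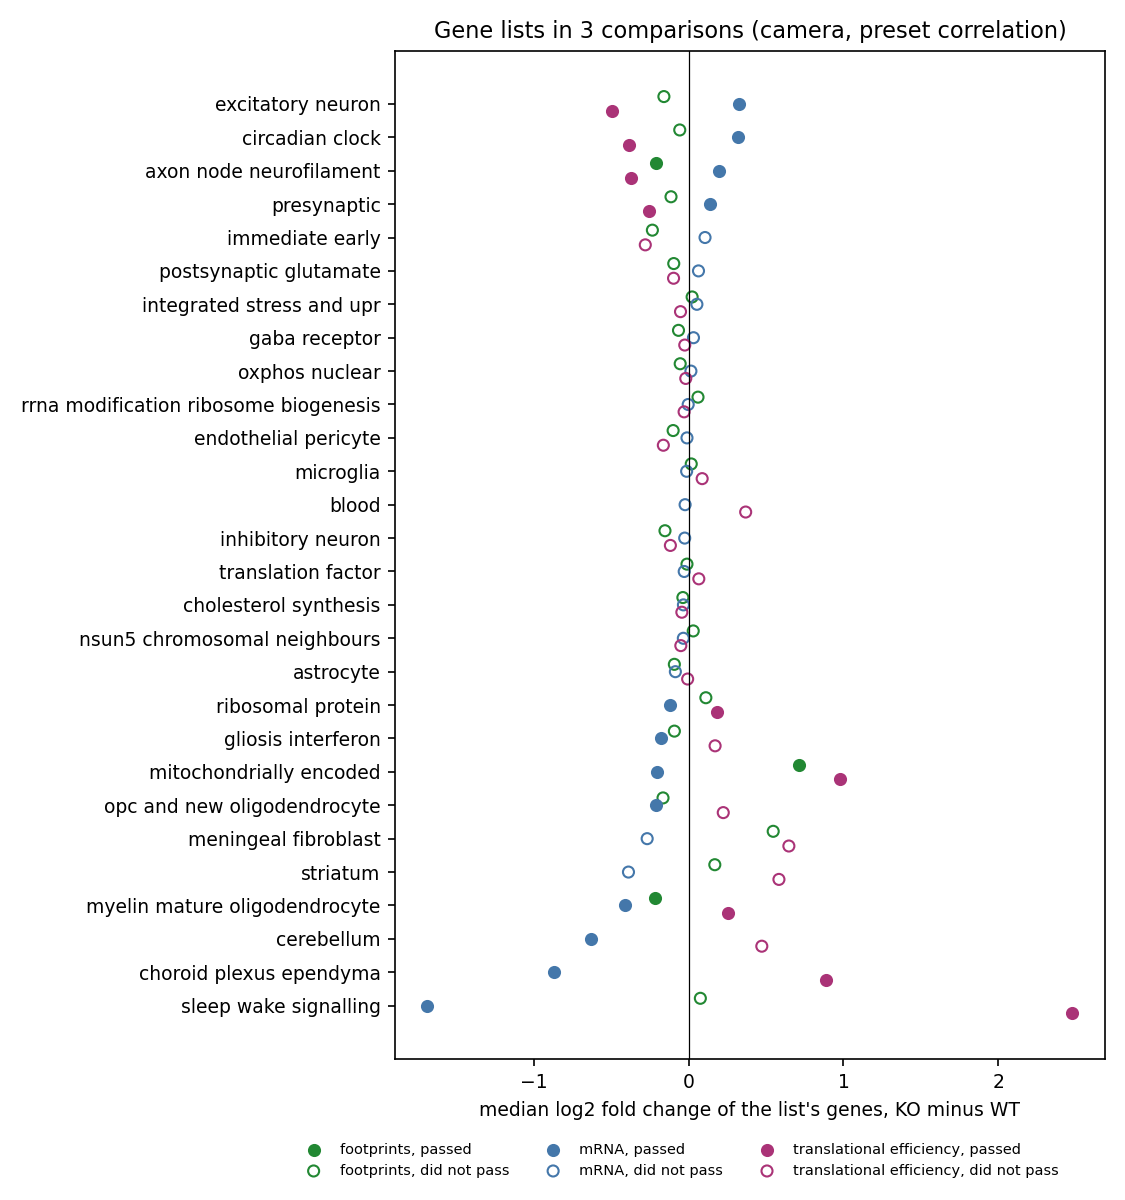
Median log2 fold change, KO minus WT (x axis), of each gene list (y axis) in footprints, mRNA and translational efficiency; filled points passed camera with its preset correlation and open points did not. The myelin list sits at −0.41 in mRNA, −0.22 in footprints and 0.25 in translational efficiency, and the mitochondrially encoded list at −0.21, 0.71 and 0.98.

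Myelin mRNA was lower in the libraries labelled KO. All 25 myelin and mature oligodendrocyte genes had a negative log2 fold change, with a median of −0.41, and the list's level fell from 6.65 ± 0.06 log2 CPM in WT to 6.24 ± 0.22 in KO without overlap of the groups (SD, n = 4, exact permutation p = 0.0286, the smallest this test can give, adjusted p = 0.160 over the lists). Mobp, a basic protein of compact myelin, had 1049 ± 27.5 CPM in WT and 781 ± 106 in KO, and Mbp 3045 ± 210 and 2292 ± 375. Clock, excitatory neuron, presynaptic and axon node transcripts were higher, and choroid plexus and ependyma, sleep and wake, ribosomal protein, mitochondrially encoded, oligodendrocyte precursor, cerebellar and gliosis transcripts were lower. These 12 lists, 4 higher and 8 lower, passed camera among 28, and 0 passed by camera with an estimated correlation (lowest adjusted p = 0.132) or by fry (0.0574). No single mRNA passed edgeR among 13058 genes, with 1377 at an unadjusted p under 0.05 where 653 are expected by chance if the model holds. Splits of 4 against 4 with as many WT as KO libraries on each side gave 160 to 2029. For KO against WT with 1 library left out, the number ran from 913 without WT library 2 to 1606 without WT library 3. DESeq2 called 75 genes, 43 higher and 32 lower, and limma on RPKM called 0.

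In the myelin list, 0 of 25 genes passed edgeR over all genes and 19 passed when adjusted over the list alone. Mal (−0.47 ± 0.09), Mobp (−0.43 ± 0.09), Ugt8a, which makes the myelin lipid galactosylceramide (−0.39 ± 0.09), and Cldn11, a tight junction protein of myelin (−0.42 ± 0.11), had the lowest p. By DESeq2, chosen after the data were seen, these 4 passed over all genes (adjusted p from 0.00214 for Mal to 0.0405 for Cldn11). The list had an adjusted p of 2.14e-25 by camera and adjusted p = 0.132 with an estimated correlation. Oligodendrocyte precursor and newly formed oligodendrocyte genes were lower too (17 of 18, median −0.21), with 1 passing when adjusted over the list alone. That was Sox10, the transcription factor of the oligodendrocyte lineage (−0.49 ± 0.12), and the list had adjusted p = 2.78e-07 by camera and adjusted p = 0.132 with an estimated correlation. Markers of cerebral cortex stood at 5.87 ± 0.21 log2 CPM in WT and 6.23 ± 0.14 in KO (SD, n = 4, exact permutation p = 0.0571), and the median log2 fold change was −0.34 for hippocampus markers (7 of 8 below 0) and −0.88 for motile cilia markers (11 of 12 below 0). The hippocampus median ran from −0.56 without WT library 4 to −0.11 without KO library 4. Astrocyte (median −0.09), microglia (−0.01) and endothelial and pericyte (−0.01) transcripts did not pass camera. Nor did striatal (−0.39, 10 of 10 lower, adjusted p = 0.171), inhibitory neuron (−0.03), immediate early (0.10), postsynaptic (0.06), cholesterol synthesis (−0.03) or rRNA modification (−0.00) transcripts.

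Circadian clock mRNA was higher in KO (19 of 21 genes, median 0.32), and 9 genes passed when adjusted over the list alone. Bhlhe40, a repressor of the clock, had 109 ± 23.0 CPM in WT and 172 ± 19.5 in KO (SD, n = 4). Nr1d2, another clock repressor, had a log2 fold change of 0.32 ± 0.08 and Hlf, an output factor of the clock, of 0.46 ± 0.12. Excitatory neuron genes were higher (9 of 10, median 0.33, 5 adjusted over the list alone), among them Tbr1 (0.47 ± 0.12), a transcription factor of cortical projection neurons. Presynaptic genes were higher (17 of 18, median 0.14, 1 adjusted over the list alone), with Snap25, a protein of vesicle fusion, at 2353 ± 135 CPM in WT and 3011 ± 190 in KO. Axon node and neurofilament genes were higher (14 of 15, median 0.19, 4 adjusted over the list alone), with the sodium channels Scn8a (0.32 ± 0.08) and Scn1a (0.49 ± 0.14) first. Adjusted p by camera was 1.10e-11, 1.11e-06, 1.32e-05 and 4.61e-06 for the 4 lists in this order. With an estimated correlation the adjusted p was 0.132 for the first 3 and 0.197 for the axon list. Without WT libraries 1 and 2 the clock median was 0.20 and the excitatory neuron median 0.24. Cerebral cortex markers, which share no gene with the excitatory neuron list, had a median of 0.36 beside these 4 lists (9 of 10 genes above 0).

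**Figure D3:**
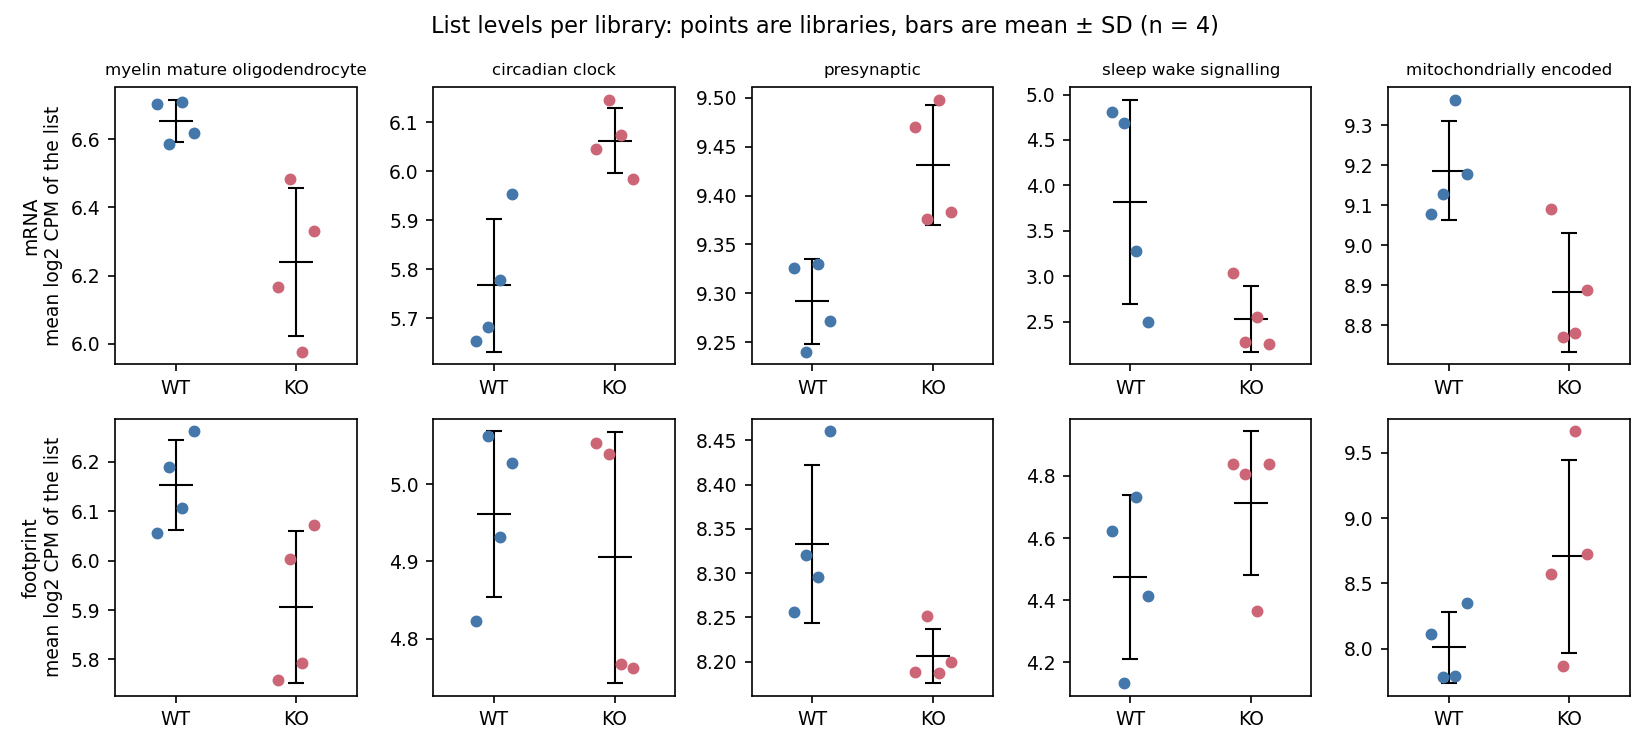
Mean log2 CPM (y axis) of 5 gene lists in each WT and KO library (x axis, points), mRNA above and footprints below, with bars for mean and SD (n = 4). In mRNA the groups do not overlap for the myelin, clock and presynaptic lists, while 2 of the 4 WT libraries carry the high sleep and wake level.

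Hypothalamic and ventricular transcripts were lower in KO mRNA and spread widely between WT libraries. In the sleep and wake list, 11 of 15 genes were lower (median −1.69), with 6 lower and 2 higher when adjusted over the list alone. Its lowest p values were those of the neuropeptide Gal (−2.19 ± 0.50), vasopressin Avp (−4.43 ± 1.02), Th, the rate-limiting enzyme of dopamine synthesis (−2.02 ± 0.59), and Pmch, a hypothalamic neuropeptide (−5.59 ± 1.67). Avp had 18.9 ± 17.6 CPM in WT and 0.882 ± 0.979 in KO (SD, n = 4). The size of the sleep and wake change depended on the filter. Over the 21 listed genes with a mean count of at least 10 the median was −0.48, with 14 lower and 7 higher. Choroid plexus and ependyma genes were lower in 11 of 11 (median −0.87), with Ccdc153, a gene of motile cilia, at −1.71 ± 0.37 as the 1 that passed when adjusted over the list alone. Adjusted p was 0.0149 and 2.78e-07 by camera and 0.198 and 0.197 with an estimated correlation. WT libraries 1 and 2 stood apart on the first principal component of mRNA (24.7 and 21.7 against −13.5 to −4.13 for the other 6), which held 34.5% of the variance. Without these 2 libraries the sleep and wake median turned to 0.14 (camera adjusted p = 0.534) and the choroid plexus median was −0.43. Leaving out WT library 2 (median −0.71, adjusted p = 0.129) or KO library 4 (0.0871) ended the sleep and wake call, and without WT library 1 its median and the change of Th were both −0.96. The choroid plexus median was −1.81 without KO library 1 and −0.56 without KO library 4.

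Cytosolic ribosomal protein mRNA was lower in KO by a small amount (66 of 77 genes, median −0.12), with Rpl10 at −0.35 ± 0.08 and Rps6 at −0.30 ± 0.07. Mitochondrially encoded mRNA was lower in 13 of 13 genes (median −0.21), with mt-Co3, a cytochrome oxidase subunit, at −0.71 ± 0.24. No gene of either list passed edgeR, over all genes or when adjusted over the list alone. By DESeq2, chosen after the data were seen, Rpl10 (adjusted p = 0.00881) and Rps6 (0.0259) passed over all genes. Adjusted p was 2.06e-08 and 3.85e-05 by camera, and 0.381 and 0.166 with an estimated correlation. Cerebellar markers (3 of 5 lower, median −0.63, 2 adjusted over the list alone), led by the transcription factor Zic1 (−1.19 ± 0.32), and gliosis and interferon genes (12 of 13 lower, median −0.18, 0 adjusted over the list alone), led by the filament protein Vim (−0.24 ± 0.09), had camera adjusted p = 0.0146 and 0.0220. With an estimated correlation their adjusted p was 0.222 and 0.354. Of the 10 listed cerebellar genes, 5 were measured. The Purkinje cell gene Pcp2 and the granule cell gene Gabra6 had 31 and 34 mRNA counts over all libraries. The change of the measured genes therefore need not stand for cerebellum. The cerebellar call ended without WT library 2 (adjusted p = 0.129), WT library 4 (0.0636) or KO library 4 (0.0594), and its median was −0.33 without WT library 1. The gliosis call ended without WT library 1 (0.148), WT library 3 (0.183) or KO library 4 (0.0652). The ribosomal protein median was −0.08 without KO library 3. Without WT libraries 1 and 2 the medians were −0.15 for the cerebellar and −0.05 for the mitochondrially encoded list.

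The single mRNAs with the lowest p did not pass edgeR. Pak7, a neuronal kinase (ENSMUSG00000039913, chromosome 2, 136081104 to 136387967), had 52.0 ± 4.10 CPM in WT and 84.6 ± 12.1 in KO (SD, n = 4), a log2 fold change of 0.70 ± 0.11 (SE, edgeR adjusted p = 0.223), and its adjusted p was 0.0123 without KO library 4. Tac2, the precursor of neurokinin B (ENSMUSG00000025400, chromosome 10, 127724478 to 127731768), had 10.6 ± 1.20 and 5.15 ± 0.854 CPM, a log2 fold change of −1.04 ± 0.15 (edgeR adjusted p = 0.223). Also on the higher side were Hecw2, a ubiquitin ligase (0.62 ± 0.10), Kcnh7, a potassium channel (0.58 ± 0.10), Drp2 (0.36 ± 0.06) and D1Ertd622e (0.36 ± 0.07). On the lower side were Efnb3, an ephrin (−0.63 ± 0.11), Tppp3, a tubulin-binding protein (−0.65 ± 0.11), Rnase4, a secreted ribonuclease (−0.51 ± 0.09), and Eif3j2 (−1.52 ± 0.26), for which reads shared with its close paralog Eif3j1 were not examined. Their edgeR adjusted p was 0.223, or 0.270 for D1Ertd622e.

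**Figure D4:**
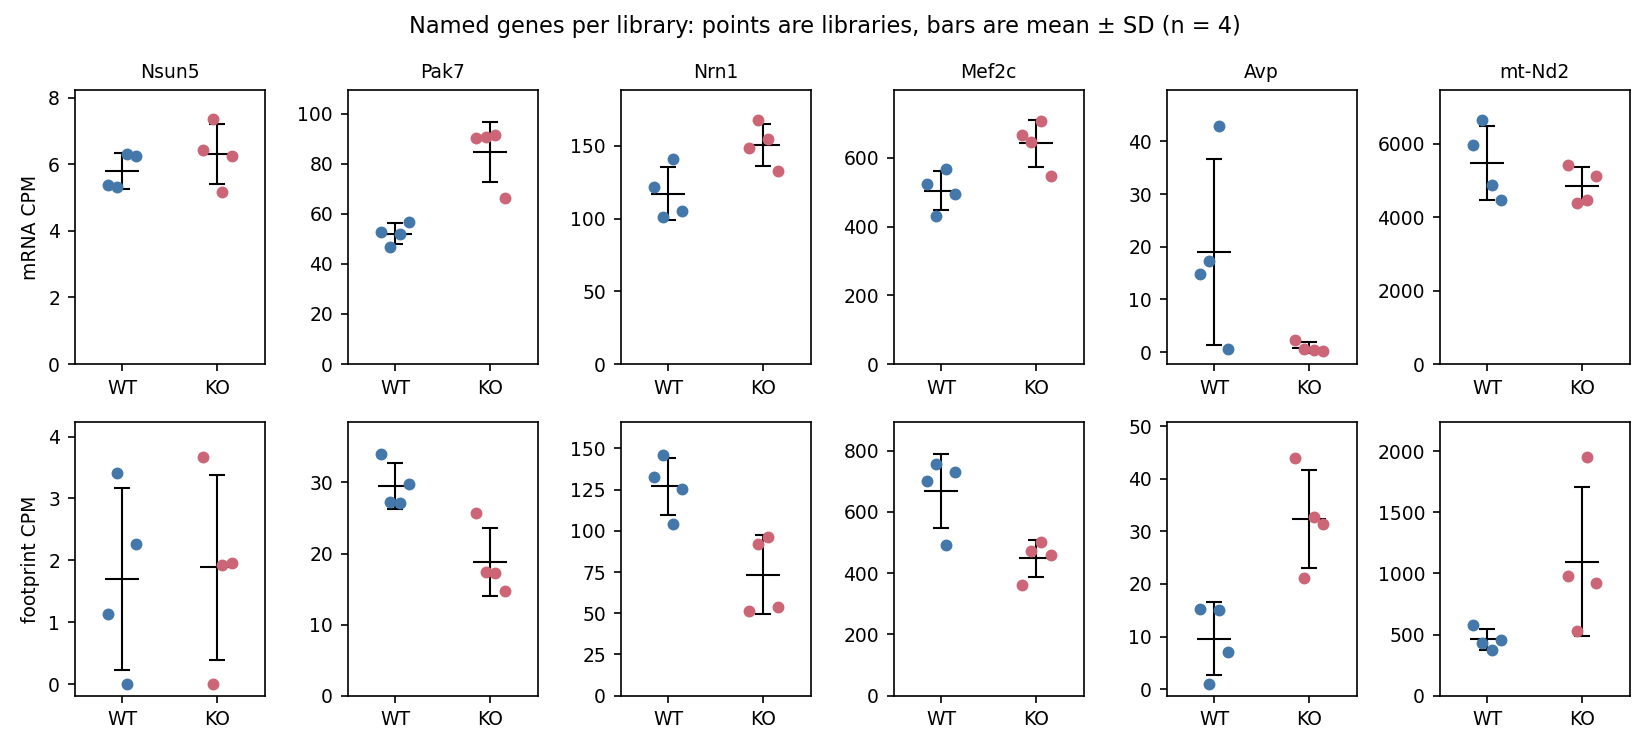
CPM (y axis) of 6 genes in each WT and KO library (x axis, points), mRNA above and footprints below, with bars for mean and SD (n = 4). Pak7, Nrn1 and Mef2c have higher mean mRNA and lower mean footprints in KO, and Nsun5 mRNA overlaps between the groups.

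Translational efficiency, the footprint change of a gene relative to its mRNA change, was lower in KO for excitatory neuron, axon node, clock and presynaptic genes. It was higher for mitochondrially encoded, sleep and wake, choroid plexus, ribosomal protein and myelin genes. Each of these lists had an mRNA median of the opposite sign, so these calls are not separate from the mRNA differences. Whether footprint and mRNA libraries hold the same tissue stays open. A difference in tissue between the library kinds therefore cannot be told apart from a change in translation in these values. Footprint medians were −0.06 for clock, 0.07 for sleep and wake, −0.12 for presynaptic, −0.16 for excitatory neuron and −0.21 for axon node genes. They were 0.11 for ribosomal protein, −0.22 for myelin and 0.71 for mitochondrially encoded genes. Choroid plexus genes were too few to test in footprints. Nrn1 had 127 ± 17.4 footprint CPM in WT and 73.3 ± 23.9 in KO against 117 ± 18.1 and 151 ± 14.4 mRNA CPM (SD, n = 4). Mef2c, a transcription factor of neurons, had 670 ± 121 and 449 ± 60.7 footprint CPM against 504 ± 57.0 and 642 ± 67.6 mRNA CPM. These 9 lists, 5 higher and 4 lower, passed camera among 28, with 0 by camera with an estimated correlation (lowest adjusted p = 0.127) and 1 by fry. No single gene passed edgeR among 9673, with 1045 at an unadjusted p under 0.05 where 484 are expected by chance if the model holds. Splits of 4 against 4 with as many WT as KO libraries on each side gave 480 to 786. The chance level of this model is therefore likely above 484. The model gave each gene 1 dispersion for both library kinds. Fitted separately, the common coefficient of variation between libraries was 0.28 for footprints and 0.14 for mRNA, against 0.15 in this model. Limma-voom with a variance factor per kind, chosen after the data were seen, called 0 genes, with 685 at an unadjusted p under 0.05. DESeq2 called 144 genes, 85 higher and 59 lower, and limma on RPKM called 0.

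Mitochondrially encoded genes had a median of 0.98 (9 of 9 higher, 8 adjusted over the list alone), with mt-Nd2 at 1.44 ± 0.33 and mt-Nd5 at 1.40 ± 0.36. Excitatory neuron genes had a median of −0.50 (9 of 10 lower, 4 adjusted over the list alone), with Nrn1 at −1.14 ± 0.23. Axon node and neurofilament genes had a median of −0.37 (14 of 15 lower, 6 adjusted over the list alone), with Scn1a at −0.69 ± 0.20. Clock genes had a median of −0.39 (17 of 19 lower), with Per2 at −1.23 ± 0.43, and presynaptic genes −0.26 (17 of 18 lower), with Rab3a, a vesicle GTPase, at −0.43 ± 0.13; in both lists 0 genes passed when adjusted over the list alone. Adjusted p by camera was 8.24e-09, 9.39e-05, 7.70e-06, 0.00144 and 0.000170 in this order, and adjusted p = 0.127 with an estimated correlation for all 5. By fry the presynaptic list passed (adjusted p = 0.0478). Cerebral cortex markers had medians of 0.36 in mRNA (9 of 10 higher) and −0.22 in footprints (4 of 9 higher), and their translational efficiency was not tested. The clock median was −0.26 without WT library 1, and mt-Nd5 stood at 0.92 without KO library 3.

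Sleep and wake genes had a median of 2.48 (10 of 14 higher, 7 adjusted over the list alone), with Avp at 6.22 ± 1.16 and Hcrt, the precursor of orexin, at 6.59 ± 2.14. Their mRNA was high in a few WT libraries, with Hcrt at 11.6 ± 16.7 CPM in WT and 0.263 ± 0.409 in KO (SD, n = 4). Avp had 9.60 ± 6.90 footprint CPM in WT and 32.3 ± 9.35 in KO, against 18.9 ± 17.6 and 0.882 ± 0.979 mRNA CPM. Its footprints and its mRNA thus moved in opposite directions. Choroid plexus and ependyma genes had a median of 0.89 (9 of 10 higher, 1 adjusted over the list alone), ribosomal protein genes 0.18 (53 of 75 higher, 1 adjusted over the list alone) and myelin genes 0.25 (22 of 25 higher, 0 adjusted over the list alone). Examples were Ccdc153 (3.01 ± 0.85), Rpl17 (1.37 ± 0.31) and the myelin regulator Myrf (0.50 ± 0.26, and 0.32 without KO library 1). Camera gave adjusted p = 0.000217, 0.00393, 0.00555 and 0.0152 for these 4 lists. With an estimated correlation the adjusted p was 0.127, 0.445, 0.470 and 0.470. The sleep and wake median was 1.11 without WT library 1 and 1.37 without WT library 2. In footprints, 2 of the 12 listed choroid plexus and ependyma genes reached a mean count of 10. The choroid plexus call ended without KO library 2 (adjusted p = 0.160) or KO library 4 (0.134), with a median of 1.64 without KO library 1, and the ribosomal protein call ended without WT library 3 (0.0801) or KO library 3 (0.0552, median 0.11), with a median of 0.29 without WT library 1. The myelin call ended without WT library 1 (0.0828), WT library 3 (0.122, median 0.15), KO library 3 (0.0760, median 0.13) or KO library 4 (0.0562, median 0.15).

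Among single genes, Pak7 had a translational efficiency change of −1.35 ± 0.24 and Avp of 6.22 ± 1.16 (log2, SE, n = 4 each, edgeR adjusted p = 0.0939 for both). Pak7 had 29.5 ± 3.21 footprint CPM in WT and 18.8 ± 4.75 in KO. Csf2ra (2.54 ± 0.52), Yipf1 (2.19 ± 0.45), Nrn1 (−1.14 ± 0.23) and Mef2c (−0.91 ± 0.19) followed with edgeR adjusted p = 0.106. Csf2ra rested on few footprints, with mean counts of 3.25 in WT and 6.5 in KO. Asap1, a regulator of membrane traffic (−0.86 ± 0.18), had 0.114, and Cinp (1.21 ± 0.26), Rpl17 (1.37 ± 0.31) and Kcnh7 (−1.0 ± 0.22) had 0.165. Avp passed with a replicate block (adjusted p = 0.0443), with no filter on low values (0.0412) and by DESeq2 (0.00760), and did not pass in a limma fit of the log2 ratio per number (0.654), which called 0 of 9673 genes with 689 at an unadjusted p under 0.05. Avp also passed without WT library 4 (adjusted p = 0.00373), Mef2c without WT library 3 (0.0217), and Yipf1 (0.0266), mt-Nd4 (0.0266) and mt-Nd2 (0.0299) without KO library 2.

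Over 8123 genes tested in both kinds of library, the footprint and mRNA log2 fold changes had a Pearson r of −0.113 and a Spearman rho of −0.103, across genes, which are not independent replicates. The mean log2 CPM of 9673 genes correlated at r = 0.793 between footprints and mRNA. As shares of each library's footprint counts, mitochondrially encoded genes took 0.359% ± 0.139 in WT and 0.509% ± 0.271 in KO, myelin genes 0.423% ± 0.127 and 0.296% ± 0.121, ribosomal protein genes 0.212% ± 0.0616 and 0.196% ± 0.0785, and blood genes 0.00199% ± 0.00181 and 0.00162% ± 0.000681 (SD, n = 4). The 10 most abundant genes took 37.4% ± 11.7 and 42.8% ± 12.02. Without KO library 3 the difference in the mitochondrially encoded share went from 0.151 to 0.0181 percentage points, and the difference in the share of the 10 most abundant genes ran from 0.584 without WT library 1 to 11.2 without KO library 2. The ribosomal protein difference ran from −0.0534 without KO library 2 to 0.0118 without WT library 1, the blood difference from −0.000736 without WT library 4 to 0.000531 without WT library 2, and the myelin difference was −0.0750 without WT library 1. None of these 5 shares passed the exact permutation test (lowest adjusted p = 0.857).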

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

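Chosen only after the data were seen were the tests without WT libraries 1 and 2 (myelin list, sleep and wake list, hypothalamus and motile cilia markers), the myelin level with cortex markers as a covariate, and DESeq2 for mRNA and translational efficiency.

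Of 202 groups of 4 libraries searched for a library far from the other 3, 9 held one, and chance flags about 1 in 20 groups (10.1 here), so their number gives no sign beyond chance. KO library 3 had the lowest footprint total of its group, 586392 counts against 1230192 to 1296876. WT library 2 had the highest share of blood gene footprints, 0.00469% against 0.000888% to 0.00120%. In footprints, the axon node list stood at 6.37 log2 CPM in WT library 1 (others 6.64 to 6.66), the sleep and wake list at 4.37 in KO library 3 (4.81 to 4.84) and the cholesterol synthesis list at 5.06 in KO library 1 (5.34 to 5.37). In mRNA, blood genes stood at 4.18 log2 CPM in KO library 1 (2.90 to 2.98) and the chromosomal neighbours of Nsun5 at 5.43 in WT library 4 (5.34 to 5.35). KO library 4 had the lowest mRNA of the kinase Pak7, 66.5 CPM (90.3 to 91.4), and of the cytokine receptor Csf2ra, 8.14 CPM (8.85 to 8.90). No explanation was tested for these 9.

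Lower myelin mRNA in the libraries labelled KO (Mbp, Mobp, Mal and the other 22 genes of the list) held against 2 technical explanations. Without WT libraries 1 and 2, which stand apart in mRNA, the median was −0.38 with 25 of 25 genes lower, and 0% of 10000 random lists matched in length and level had a median as low (lowest −0.12). Members of the random lists were drawn independently, while the estimated correlation within the myelin list was 0.50. The 0% therefore bears on length and level bias and says nothing on chance. Less brainstem tissue in KO remains open, since 2 of 19 hindbrain markers had enough counts. A median above 0, with all libraries and without each in turn, had been set down beforehand as arguing against it. Theirs was 1.33, and from 0.99 to 2.27 with 1 library left out, but 2 genes are too few for that. A larger cortical share also remains open, because the difference was −0.40 with cortex markers as a covariate but its 95% interval reached from −0.89 to 0.09. Loss of Nsun5 may lower myelin transcripts, and a difference in dissected tissue cannot be told apart from it here, nor was library quality tested: KO libraries 3 and 1, with the lowest myelin levels (5.98 and 6.17 log2 CPM), had the highest microRNA shares of mRNA counts (0.0579% and 0.0247%, others 0.00664% to 0.0104%), and KO library 3 an rRNA share of 0.193% (others 0.0201% to 0.0345%).

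Lower hypothalamic mRNA (Avp, Gal, Pmch, Hcrt) is consistent with a difference in the tissue of the mRNA libraries, while lower ventricular mRNA (Ccdc153) is left open. Markers of hypothalamus written down before the test had a median of −1.59 (7 of 8 lower), from −2.23 to −1.11 when each library was left out and −0.66 without WT libraries 1 and 2. Over the 21 sleep and wake genes with a mean count of at least 10, the median was −0.48 in all libraries and 0.15 without these 2. Motile cilia markers stayed at −0.66 without them, with 11 of 12 lower. Whether mRNA and footprint libraries of 1 number hold the same tissue stays open, with r = 0.648 between their choroid plexus levels (8 numbers, 2 genes, exact permutation p = 0.0556; r = 0.827 without KO libraries 1 and 4). Loss of Nsun5 acting on hypothalamic neurons was not tested and stays open, and so does the sleep trait.

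Other splits of the 8 libraries were compared with the real one for the counts of lists that passed camera. For translational efficiency the real split gave 9 lists and the highest other 7. So 1 of 35 splits was as large, which met the rule set beforehand against chance. That is the smallest share 35 splits can give, it is not adjusted over the counts examined, and with an estimated correlation 0 lists passed. The splits therefore do not exclude chance for this count. For lists in mRNA the real count was 12 and the highest other 14 (10 splits as large), and for lists in footprints 3 and 3 (6 splits), so chance cannot be excluded for these counts. For single genes by edgeR the real count was 0 in each comparison, so all 35 splits are as large by construction and say nothing on chance; the highest others were 24 in footprints, 3 in mRNA and 1 in translational efficiency. At an unadjusted p under 0.05 the real counts were 468, 1377 and 1045 (DESeq2 4, 75 and 144 at the threshold), with highest others of 625, 2029 and 850. The myelin mRNA median, in absolute size, was 0.41 in the real split and 0.34 in the highest other, and the clock mRNA median 0.32 and 0.25. For myelin the real and highest other values were 0.22 and 0.27 in footprints (3 splits as large) and 0.25 and 0.28 in translational efficiency (2 splits). For clock they were 0.06 and 0.31 in footprints (21 splits) and 0.39 and 0.30 in translational efficiency (1 split).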

How the results depend on the processing

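Chosen only after the data were seen were the settings of DESeq2 for mRNA and translational efficiency, protein-coding genes only, voom with a variance factor per library kind, 2 scalings for mRNA and translational efficiency gene counts, WT libraries 1 and 2 left out, and exact permutation of list levels. Genes past the threshold numbered 0 in each comparison by edgeR (468, 1377 and 1045 at an unadjusted p under 0.05). DESeq2 gave 4 in footprints, 75 in mRNA and 144 in translational efficiency; no filter gave 86, 24 and 2. In footprints limma on RPKM gave 5 and protein-coding genes only 3; the replicate block gave 1 in translational efficiency, Avp. Leaving out each library gave 0 in footprints, 0 to 2 in mRNA (2 without KO library 4, Pak7 and Rps27rt) and 0 to 4 in translational efficiency (1 without WT library 3 or 4, 4 without KO library 2). Lists past the threshold were 3, 12 and 9 by camera, and 0, 0 and 0 with an estimated correlation, and 0, 0 and 1 by fry; leaving out each library gave 1 to 3, 10 to 14 and 8 to 11. The myelin mRNA median of −0.41 had adjusted p = 0.132 with an estimated correlation and 0.0574 by fry. Exact permutation of list levels gave 0 and 0 lists in footprints and mRNA, and −0.41 with adjusted p = 0.160 for myelin mRNA; its smallest p of 0.0286 leaves almost no room to pass over this many lists, so this says nothing on stability. The cause was not tested for any of these changes. The sleep and wake mRNA median reversed to 0.14 without WT libraries 1 and 2; the cause was not tested. Of 150 list values under other settings, 87 kept their call, 62 lost it (15 of them in that permutation) and 1 reversed; of 192 with a library left out, 168 kept it and 24 lost it. Each called list's median kept its sign under both other scalings. Nsun5 did not pass in any setting, with leave-one-out ranges of −0.87 to 0.51 in footprints and 0.04 to 0.21 in mRNA. On simulated data with the depth and spread of the footprints, 4% of 1.5-fold changes in single genes were recovered; depth alone was not varied.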

Other observations

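No test in this part was chosen only after its result was seen, and the counts of regional markers were read without a test. Over all 8 mRNA libraries, with 134 M counts (M, mega), the 10 cerebellar genes had from 31 to 4720 counts, 3 of them under 100. Zic1 (4720), Grm4 (4512), Zic2 (2300), Cbln1 (1972) and Car8 (1799) were the higher ones, and the Purkinje cell gene Pcp2 (31), the granule cell receptor subunit Gabra6 (34) and Fat2 (64) the lower ones. Of 6 olfactory bulb genes, Th had 1184 and Cdhr1 1075, and Eomes and Tbx21 were under 100 with 36 and 15. Of 8 pituitary genes, 6 had under 100, with the hormones Gh at 7 and Prl at 0, and Pomc had 150. Of 19 hindbrain and brainstem genes, 17 had under 100, and the glycine receptor subunit Glra1 and the glycine transporter Slc6a5 had 321 and 289. The genes come from lists of regional markers written before the counts were read.

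Transcripts of exocrine glands of the head were found in the footprint libraries. Mucl2 had 17128 footprint counts and 0 mRNA counts over all libraries, the odorant-binding protein Obp1a 8018 and 0, the secretoglobin Scgb1b2 4561 and 0, and the salivary protein Bpifa2 1536 and 0, genes named after their values were seen. The share of all listed gland genes in protein-coding footprints was 0.0384% in WT library 1, 1.25% in WT library 2, 0.118% in WT library 3 and 0.143% in WT library 4, and 2.75%, 0.422%, 0.232% and 1.10% in KO libraries 1 to 4, against at most 0.000772% of mRNA. RNA of such a gland in the footprint libraries is a candidate source: of 33 further gland genes listed before they were looked at, 30 are in the table, and 11 had at least 50 footprint counts and under 10 mRNA counts. Secretoglobin and Esp genes have close paralogs, and reads shared between them were not examined. Whether the share differs with genotype stays open (0.389% ± 0.579 in WT and 1.13% ± 1.15 in KO, SD, n = 4, exact permutation p = 0.257). The libraries with the largest shares also stood highest on the first principal component of footprints, which held 30.2% of the variance. These were KO library 1 (21.9), WT library 2 (8.67) and KO library 4 (4.63), and a link was not tested. Without a filter on low counts, edgeR called 86 footprint genes, 74 higher and 12 lower in KO, with Obp1a, Scgb1b2 and Bpifa2 among them, and how the RNA came to be there was not tested.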
